A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

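Total RNA was extracted with hot phenol from yeast cultures, depleted of ribosomal RNA with a RiboMinus kit, and made into strand-specific libraries from 125 ng with a TruSeq Stranded Total RNA kit, per the labels' protocols. Paired reads of 2 × 50 nt were sequenced on a HiSeq 2500, per the labels' protocols. The reads were aligned with TopHat to build R64, per the submitters' processing notes, which name these tools without a role. The version of TopHat, the counting program, the handling of strand and of reads that match several places, and the reference of the normalization are not given in the sources used here.

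The authors deposited 1 table with 6192 features (5795 genes, 299 tRNA genes, 77 snoRNAs, 15 other ncRNAs and 6 snRNAs), each with a normalized density signal per library and a read count, per the file headers. The density signal equalled the scaled read count divided by the feature length in every library, with a largest difference of 1.16e-11. Read counts as deposited were whole in the first gat1Δ proline library and, in the other libraries, whole multiples of 1 step per library, so that the authors had scaled each library to nearly the total over genes of gat1Δ proline replicate 1 (11822090 reads). Whole reads were recovered for 100% of the positive values within a tolerance of 0.01 reads. The recovered reads came to 17480765 and 27217650 in gat1Δ glutamine, 17009715 and 28842495 in gat1Δ proline, and 34718641 and 30172764 in dal80Δ glutamine, in the order of replicates 1 and 2. A further 6 columns of values for groups were not used. Of 5809 identifiers found in a RefSeq R64 annotation, 5777 (99.4%) had the same start and end. The labels call the replicates biological. Samples were grouped by their titles, which give strain, medium and replicate number.

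The replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 41.8 in gat1Δ glutamine, 71.5 in gat1Δ proline and 50.8 in dal80Δ, so that no pair is the same library counted again. That the cultures were separate rests on the labels. Their Pearson r across genes was 0.992, 0.988 and 0.995.

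Genes with at least 10 scaled reads in at least 2 libraries were tested with limma 3.58.1 in R 4.3.3, on log2 of the density plus a pseudocount of 0.0229, the 5th percentile of positive gene densities, with an intensity trend in the prior variance. All 6 libraries entered the fit with the group as the only factor, which left 3 residual degrees of freedom, and 3 contrasts were taken. P-values were adjusted by the Benjamini-Hochberg method over all genes of a contrast, with a threshold of 0.05. This is the test planned for a file without whole counts; the quasi-likelihood test of edgeR 4.0.16 had been planned first for whole counts and was run on the recovered reads as an added alternative. It called 3573 genes for proline against glutamine, 450 for dal80Δ against gat1Δ in glutamine and 3893 for dal80Δ glutamine against gat1Δ proline. Noncoding transcripts were tested in the same way in a separate fit. Gene lists were tested with camera at a preset correlation of 0.01 on the same log2 densities, where log2 CPM had been planned, and adjusted over the 26 lists of a contrast. They were tested again with an estimated correlation. Several lists share genes, as the nitrogen-regulated permeases and the targets of nitrogen catabolite repression do, so their results are not independent. Lists and the rule for named genes were fixed before the data were examined; CAR9, ATG39, ATG40 and ATG42 were not found under those names. The rule took the deleted genes and 3 further regulators, the 10 largest rises and falls per comparison against gat1Δ glutamine among genes past the threshold with a mean of at least 5 CPM and no overlap between groups, up to 3 members per list with the smallest adjusted p and the largest opposite change, 3 noncoding transcripts each way, 5 shared and 5 opposite genes, and 5 each way in the third comparison.

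Alternatives covered the low-count filter, the pseudocount, TMM, RLE and snoRNA scaling, edgeR, DESeq2 1.42.0, stricter thresholds, the replicate number as a block and each library left out. TMM factors, a trimmed mean of log ratios that assumes most genes unchanged, came from the recovered reads. In simulated data with 200 genes changed by known folds, drawn from the real means, library sizes and spread, the limma test for proline against glutamine recovered 35.8% of genes changed 1.5-fold, 95.5% at 2-fold and 100% at 4-fold, with 17 false calls among 170 (10%). For dal80Δ against gat1Δ in glutamine it recovered 23.9%, 85.1% and 100%, with 11 false calls among 150 (7.33%). The false share lay above the nominal 5% in both, each from a single draw. The real proline comparison called 4006 genes, far more than the 200 changed here, so the draws do not give its false share.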

Results

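Strand-specific sequencing of rRNA-depleted total RNA measured the transcripts of budding yeast, Saccharomyces cerevisiae, lacking one of a pair of GATA-family transcription factors. Gat1 is known as an activator of genes for the use of poor nitrogen sources, and Dal80 as a repressor of many of the same genes. Both act in nitrogen catabolite repression, the shutdown of such genes while a preferred nitrogen source such as glutamine is present. The 6 libraries fell into 3 groups of 2 biological replicates, namely gat1Δ cells in medium containing glutamine, gat1Δ cells in medium containing proline, and dal80Δ cells in medium containing glutamine. No wild-type library and no dal80Δ library from proline was analysed here, so no difference between the strains can be assigned to either deletion alone. The libraries held between 17009715 and 34718641 recovered reads over 6192 features, of which 5594 protein-coding genes and 250 noncoding transcripts were tested. Genes took 77.7% ± 0.592 of the reads of gat1Δ glutamine libraries, 68.2% ± 1.84 in gat1Δ proline and 75.3% ± 2.18 in dal80Δ glutamine (SD, n = 2). Levels are given as scaled reads, which the authors brought to nearly the same total over genes in every library, close to that of gat1Δ proline replicate 1 (11822090 reads), with the SD over n = 2 libraries. Log2 fold changes are those of densities plus a pseudocount, with their standard errors (SE), and understate the change of low genes.

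The deleted genes were read first. GAT1 (YFL021W, build R64, chromosome 6, 95966 to 97498, plus strand) had 2 and 2 reads in the gat1Δ glutamine libraries, 3 and 2 in gat1Δ proline, and 1603 and 1062 in dal80Δ. The ratio of dal80Δ to gat1Δ in glutamine was 473, with an exact 95% Poisson interval of 185 to 1738. DAL80 (YKR034W, chromosome 11, 506898 to 507707, plus strand) had 1 and 0 reads in the dal80Δ libraries, and a count of 0 allows up to 3 reads. In gat1Δ cells it had 2 and 1 reads in glutamine and 195 and 497 in proline, a ratio of 258 with an interval of 87.8 to 1252. DAL80 was therefore near the floor in all 4 glutamine libraries, whether deleted or not, so its reads do not show the deletion apart from the effect of the medium. The intervals and floors cover counting error only, since these reads carry no molecular identifiers. The other GATA factor genes GLN3 and GZF3, and URE2, whose product holds Gln3 in the cytoplasm, were read in every library. GLN3 (chromosome 5, 229795 to 231987) stood at 426 ± 61.2 scaled reads in gat1Δ glutamine, 2246 ± 776 in gat1Δ proline and 305 ± 0.362 in dal80Δ glutamine.

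**Figure D1:**
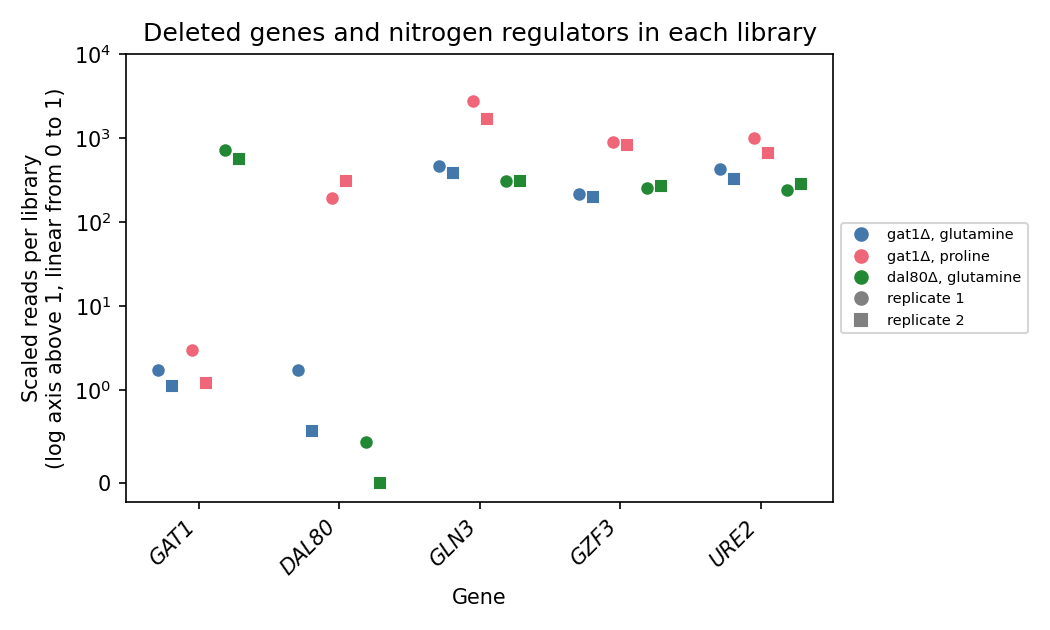
Scaled reads of GAT1, DAL80, GLN3, GZF3 and URE2 in each of the 6 libraries, on an axis that is logarithmic above 1 and linear from 0 to 1, with colour for the group and shape for the replicate. GAT1 reached 637 ± 103 in dal80Δ against 1.43 ± 0.451 in gat1Δ glutamine (SD, n = 2), and DAL80 reached 250 ± 77.4 in gat1Δ proline.

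The first comparison asked how transcript levels differed between proline and glutamine in cells without Gat1. Genes for taking up and breaking down poor nitrogen sources held the largest rises in proline. PUT1 (YLR142W, chromosome 12, 425186 to 426616), the proline oxidase gene, rose from 57.9 ± 6.29 to 25892 ± 9942 scaled reads, a log2 fold change of 8.11 ± 0.23 (SE, adjusted p = 6.25e-08). MEP2 (YNL142W, chromosome 14, 357453 to 358952), an ammonium permease gene, rose from 371 ± 33.7 to 93000 ± 20428 (log2 7.83 ± 0.22, adjusted p = 6e-08). The general amino acid permease gene GAP1 (YKR039W, chromosome 11, 515063 to 516871) rose from 1207 ± 26.9 to 83843 ± 22122 (log2 6.04 ± 0.19). Of 5594 genes, 4006 passed an adjusted p of 0.05 in limma's moderated test, 3162 of them higher and 844 lower in proline. The median gene lay at a log2 fold change of 0.50, so the direction of small changes depends on the scaling. With densities rescaled by TMM factors the median was 0.06 and 3558 genes passed, 1889 higher and 1669 lower. Rescaling by snoRNA totals gave a median of 0.23 and 2465 genes, 1650 higher and 815 lower. The libraries of both groups did not overlap for 4840 genes (86.5%), where chance gives 33.3% for any single gene. The shift of the median gene moves this share too, so the excess does not count changed genes.

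The largest rises held other transport and catabolic genes as well. DAL3 (log2 6.58 ± 0.15), for an allantoin pathway enzyme, DUR3 (6.39 ± 0.16), for urea uptake, and DIP5 (6.18 ± 0.18), for glutamate and aspartate uptake, were among the 10 largest, with ECM13 (5.66 ± 0.23). The remaining members were the mating genes MFA1 (6.48 ± 0.14), AGA2 (6.41 ± 0.26) and MFA2 (5.94 ± 0.17). The largest falls were those of BAP3 (YDR046C, chromosome 4, 548762 to 550576), a permease gene for branched-chain amino acids, which went from 3140 ± 440 to 9.82 ± 2.57 scaled reads (log2 -5.95 ± 0.14), and of the cell wall protein gene CWP1 (-4.24 ± 0.19). They were followed by MUP1 (-3.92 ± 0.17), for methionine uptake, MET3 (-3.89 ± 0.25), for ATP sulfurylase, RNR1 (-3.77 ± 0.21), for ribonucleotide reductase, and INO1 (-3.57 ± 0.47), for inositol synthesis. TDH2 (-3.53 ± 0.20), TAT1 (-3.47 ± 0.16), HXK1 (-3.46 ± 0.24) and YCL042W (-3.10 ± 0.14) completed the 10. YCL042W shares 106 bases with GLK1 on the same strand, so its reads are uncertain.

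All 9 genes of allantoin and urea catabolism rose (median log2 4.41, camera adjusted p = 9.45e-05; adjusted p = 0.439 with an estimated correlation). All 4 proline utilization genes rose, among them PUT2 (3.58 ± 0.12) and the permease gene PUT4 (4.35 ± 0.17), with a camera adjusted p = 0.00665 and an adjusted p = 0.439 with an estimated correlation. Both counts were 9 and 4 when adjusted over the list alone and after TMM rescaling. Of 46 targets of nitrogen catabolite repression, 34 rose, 5 fell and 7 did not pass (camera adjusted p = 0.00035; adjusted p = 0.439 with an estimated correlation), and 39 passed adjusted over the list alone. The largest fall among them was that of CAR2 (-2.15 ± 0.14), for arginine breakdown, and TMM rescaling gave 32 higher and 9 lower. Of 17 nitrogen-regulated permease genes 13 rose, including DAL5 (4.85 ± 0.13), and 4 fell, led by MUP1 (camera adjusted p = 0.0338; adjusted p = 0.686 with an estimated correlation). All 17 passed adjusted over the list alone, and TMM rescaling kept the counts at 13 and 4. Of 18 genes for GATA factors and nitrogen regulators 16 rose and none fell (camera adjusted p = 0.00252; adjusted p = 0.6 with an estimated correlation), with 16 adjusted over the list alone and 15 after TMM rescaling. UGA3 (4.19 ± 0.17), the activator of GABA catabolism genes, DAL80 (3.74 ± 0.19), GLN3 (2.23 ± 0.22), GZF3 (1.87 ± 0.13) and URE2 (1.08 ± 0.21) were among them, while GAT1 itself stood at 0.03 ± 0.15.

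Of 10 genes of GABA, glutamate and glutamine metabolism 7 rose, such as GLN1 (4.17 ± 0.14), for glutamine synthetase, and GDH2 (3.44 ± 0.13), for a glutamate dehydrogenase, while GAD1 (-1.45 ± 0.13) fell. The list did not pass camera (adjusted p = 0.0984), and 8 members passed adjusted over the list alone. Of 43 amino acid biosynthesis genes under general control 37 rose and 3 fell (camera adjusted p = 0.000422; adjusted p = 0.61 with an estimated correlation). ARG1 (3.56 ± 0.19) and ARG5,6 (3.20 ± 0.17), for arginine synthesis, and BAT2 (3.34 ± 0.14), a transaminase gene, rose, and SER3 (-1.34 ± 0.15), which shares 77 bases with SRG1 on the same strand, fell. The count was 40 adjusted over the list alone, and TMM rescaling gave 30 higher and 5 lower. Of 41 ribosome biogenesis genes 37 rose and none fell (median log2 1.08, camera adjusted p = 0.000199; adjusted p = 0.688 with an estimated correlation), with NOP15 (2.46 ± 0.18) and DBP2 (2.22 ± 0.17) as examples. There were 37 adjusted over the list alone, and 25 were higher after TMM rescaling. Of 14 retrograde response genes 11 rose and 1 fell (camera adjusted p = 0.0432; adjusted p = 0.439 with an estimated correlation), led by CIT2 (3.25 ± 0.12), for peroxisomal citrate synthase. Without gat1Δ glutamine replicate 1 the camera calls of this list and of the nitrogen-regulated permeases ended, each at an adjusted p = 0.0558. The list had 12 past the threshold adjusted over the list alone, and TMM rescaling gave 9 higher and 3 lower.

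Genes of glycolysis fell almost as a whole. Of 19, 18 fell and only PDC5 (0.42 ± 0.15) rose, a call that ended and turned to -0.0570 after TMM rescaling (camera adjusted p = 7.88e-17; adjusted p = 0.439 with an estimated correlation). TDH2 dropped from 78337 ± 1410 to 6933 ± 2093 scaled reads, and ENO1 (-2.56 ± 0.16) and ENO2 (-2.84 ± 0.19) fell as well. The TDH and ENO genes have near-identical copies, so the split of reads among them is uncertain. Of 10 histone genes 9 fell and none rose (camera adjusted p = 4.64e-08; adjusted p = 0.439 with an estimated correlation), including the linker histone gene HHO1 (-1.92 ± 0.15) and HTB2 (-2.57 ± 0.25), which also belongs to a family of near-identical copies. Of 13 permease genes and regulators under the SPS sensor of external amino acids 7 fell and 4 rose, with BAP3 lowest and DIP5 highest (camera adjusted p = 0.00721; adjusted p = 0.555 with an estimated correlation). Of 23 genes of sulfur amino acid synthesis 13 fell, among them MET3, MET6 (-1.50 ± 0.14) and SAM2 (-2.46 ± 0.23), and 8 rose, led by STR3 (2.13 ± 0.34), with a camera adjusted p = 0.000187 and an adjusted p = 0.439 with an estimated correlation. Of 34 general stress genes 18 fell, such as GLK1 (-2.84 ± 0.19) and TPS1 (-1.59 ± 0.16), and 11 rose, led by DDR2 (2.62 ± 0.30), with a camera adjusted p = 2.3e-05 and an adjusted p = 0.51 with an estimated correlation. In these lists 19 glycolysis, 9 histone, 12 SPS, 21 sulfur and 29 stress genes passed adjusted over the list alone. TMM rescaling gave 18 lower and 0 higher in glycolysis, 10 lower histone genes, 7 lower and 4 higher SPS genes, 14 lower and 4 higher sulfur genes, and 21 lower and 6 higher stress genes.

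The counts of several other lists depended on the scaling, and the balance of rises and falls turned for the tricarboxylic acid cycle and for arginine and asparagine catabolism. Of 137 ribosomal protein genes, many of them near-identical pairs, 44 fell and 21 rose (camera adjusted p = 1.64e-08; adjusted p = 0.61 with an estimated correlation), while TMM rescaling gave 92 lower and 3 higher. Of 15 genes of the tricarboxylic acid cycle 5 rose, led by IDH1 (2.46 ± 0.12) and IDH2 (2.32 ± 0.12), and 2 fell, against 3 higher and 9 lower after TMM rescaling (camera adjusted p = 0.461). Of 34 respiratory chain and ATP synthase genes 21 rose and 2 fell, against 9 and 7 (camera adjusted p = 0.419). Of 7 genes of arginine and asparagine catabolism 4 rose and 2 fell, against 0 and 3 (camera adjusted p = 0.301), and the 4 ASP3 copies among them cannot be told apart by their reads. Of 22 autophagy genes 14 rose, led by ATG1 (2.41 ± 0.30), against 8 higher and 1 lower after TMM rescaling (camera adjusted p = 0.202). Of 20 iron regulon genes 13 rose and 1 fell, against 9 and 5 (camera adjusted p = 0.328). Of 14 phosphate response genes 10 rose and 1 fell, against 7 and 3 (camera adjusted p = 0.498), with the phosphate transporter genes PHO84 (4.83 ± 0.50) and PHO89 (3.99 ± 0.47) highest. Of 9 vacuolar protease genes 3 fell and 2 rose, against 5 and 1 (camera adjusted p = 0.0742). Of 16 meiosis genes tested 7 rose and 1 fell, against 5 and 3 (camera adjusted p = 0.901), and of 10 pseudohyphal growth genes 8 rose and 1 fell, against 7 and 1 (camera adjusted p = 0.183). Adjusted over the list alone, the numbers that passed were 52 ribosomal protein, 6 tricarboxylic acid cycle, 23 respiratory, 6 arginine and asparagine, 14 autophagy, 14 iron, 11 phosphate, 5 protease, 7 meiosis and 9 pseudohyphal growth genes.

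Genes specific to the a mating type rose in proline. All 7 rose (camera adjusted p = 0.000273; adjusted p = 0.48 with an estimated correlation), and all 7 passed adjusted over the list alone and after TMM rescaling. The pheromone receptor gene STE2 (YFL026W, chromosome 6, 82580 to 83875) went from 60.4 ± 7.41 to 2292 ± 385 scaled reads (log2 4.68 ± 0.15), and the a-factor gene MFA1 from 8.83 ± 0.103 to 1018 ± 140. Of the 4 genes specific to the α mating type 2 rose, MF(ALPHA)1 (1.89 ± 0.17) and STE3 (0.50 ± 0.18), and 2 passed adjusted over the list alone (camera adjusted p = 0.579). The call of STE3 ended after TMM rescaling, at -0.00522. Across the 26 lists 15 passed camera with its preset correlation, and 0 with an estimated one.

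**Figure D2:**
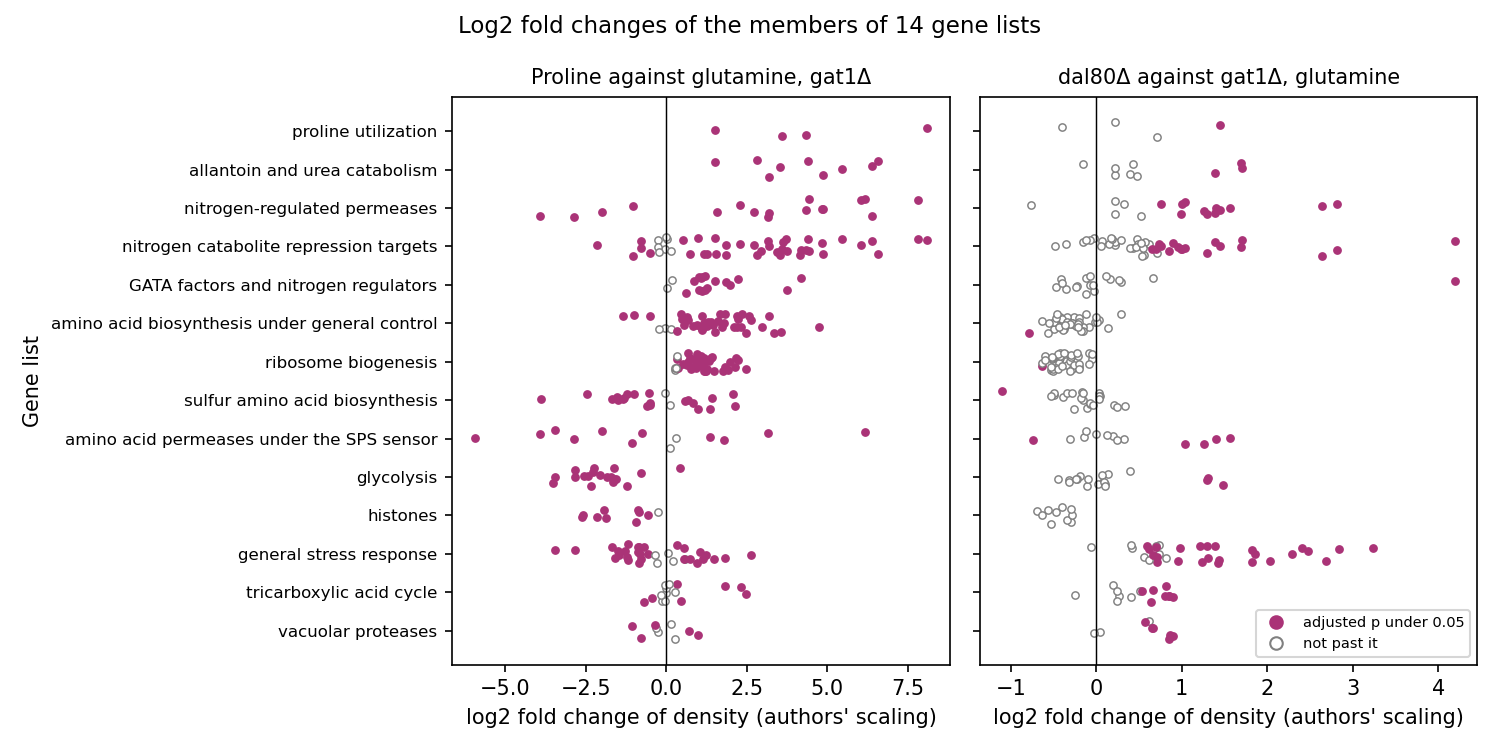
Log2 fold changes of density under the authors' scaling for the members of 14 gene lists, for proline against glutamine in gat1Δ (left) and dal80Δ against gat1Δ in glutamine (right), 1 point per gene, filled where the adjusted p was under 0.05; the panels have different horizontal axes. In proline all 9 allantoin and urea genes rose and 18 of 19 glycolysis genes fell, and in dal80Δ 25 of 34 stress genes were higher. With TMM rescaling the tricarboxylic acid cycle genes on the left were mostly lower.

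The second comparison set the strains side by side in glutamine. Nitrogen-related permease genes, stress genes and genes specific to a mating type separated them. GAP1 was higher in dal80Δ by 2.82 ± 0.19 on the log2 scale (adjusted p = 4.16e-05) and MEP2 by 2.64 ± 0.22 (adjusted p = 0.000146). The zinc transporter gene ZRT1 (YGL255W, chromosome 7, 20978 to 22108) was lower, at 789 ± 754 scaled reads against 19334 ± 1398 (log2 -4.97 ± 0.57, adjusted p = 0.00133). Of 5594 genes 305 passed, 222 higher and 83 lower in dal80Δ, and 1587 had an unadjusted p under 0.05. TMM rescaling moved the median gene from -0.15 to -0.01 and gave 396 genes, 346 higher and 50 lower. The count fell whichever library of these groups was left out, which leaves 1 library in that group, and none of the 305 calls changed sign. This does not show that the count rests on a particular library. The libraries of both groups did not overlap for 3574 genes (63.9%), where chance gives 33.3% for any single gene. A shift shared by many genes, like that of the median, moves this share, so the excess does not count changed genes.

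The strains differed in the mating type their transcripts show, and this difference goes with every other difference between them. All 7 a-specific genes were higher in dal80Δ (camera adjusted p = 7.83e-27; adjusted p = 0.123 with an estimated correlation), and all 4 α-specific genes were lower (camera adjusted p = 2.33e-11; adjusted p = 0.123 with an estimated correlation). MFA2 (YNL145W, chromosome 14, 352414 to 352530) stood at 4180 ± 321 scaled reads in dal80Δ against 5.73 ± 1.81 in gat1Δ (log2 8.97 ± 0.17), and STE2 at 10207 ± 628 against 60.4 ± 7.41. The α-factor gene MF(ALPHA)1 (YPL187W, chromosome 16, 193648 to 194145) stood at 25.1 ± 6.62 against 15468 ± 1571 (log2 -8.74 ± 0.17). MFA1, AGA2, BAR1 and STE6 were also among the 10 largest rises, and MF(ALPHA)2, SAG1 and STE3 among the 10 largest falls. Both lists passed whole, with 7 and 4 genes, adjusted over the list alone, and TMM rescaling gave 7 higher and 4 lower. The other largest rises were those of YCL048W-A (5.10 ± 0.29), GAT1 (4.19 ± 0.15), TKL2 (3.40 ± 0.16), a transketolase gene, and DDR2 (3.23 ± 0.30). The other largest falls were those of ZPS1 (-5.18 ± 0.29), ZRT1, YLR040C (-4.12 ± 0.14), VEL1 (-2.53 ± 0.40), SPO14 (-1.30 ± 0.16) and ZAP1 (-1.26 ± 0.21), the last for the activator of zinc uptake genes.

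**Figure D3:**
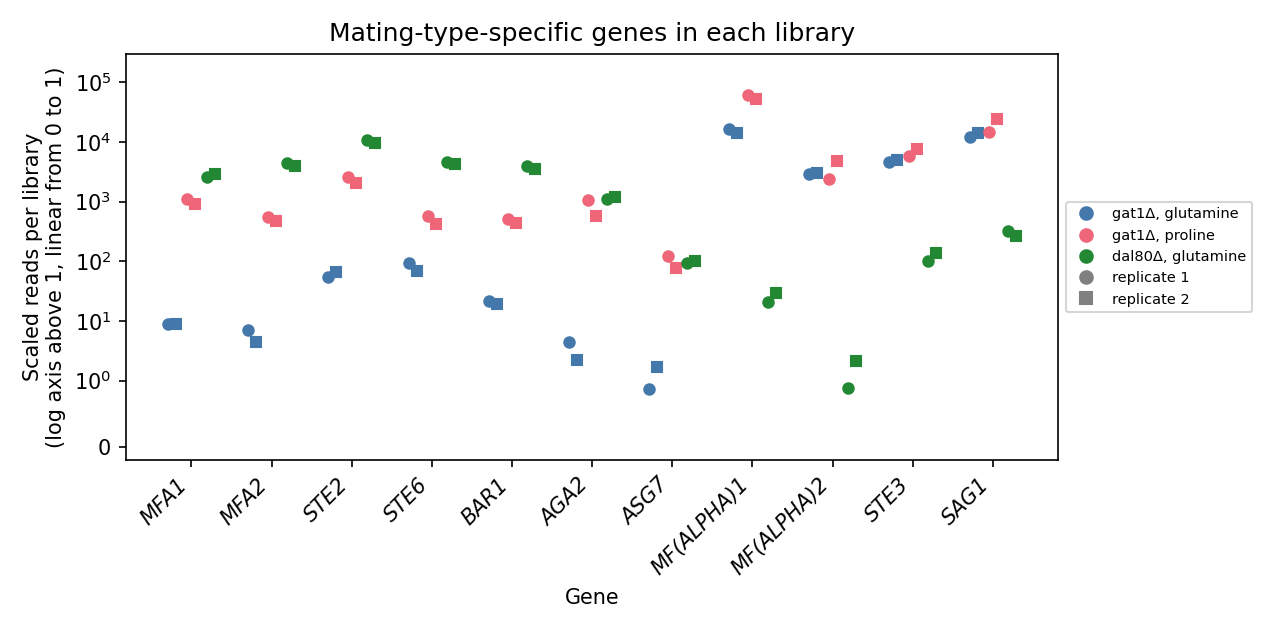
Scaled reads of 7 genes specific to the a mating type (MFA1 to ASG7) and 4 specific to the α mating type (MF(ALPHA)1 to SAG1) in each of the 6 libraries, on an axis that is logarithmic above 1 and linear from 0 to 1, with colour for the group and shape for the replicate. The a-specific genes were high in dal80Δ, low in gat1Δ glutamine and, as for STE2 at 2292 ± 385 (SD, n = 2), raised in gat1Δ proline, while the α-specific genes were high in both gat1Δ groups.

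Of the 46 targets of nitrogen catabolite repression 18 were higher in dal80Δ, none lower and 28 did not pass (camera adjusted p = 2.42e-23; adjusted p = 0.123 with an estimated correlation). One of the 18 is GAT1, which is deleted in the other strain. There were 28 adjusted over the list alone, and TMM rescaling gave 24 higher. Of 17 nitrogen-regulated permease genes 12 were higher and none lower (camera adjusted p = 4.4e-17; adjusted p = 0.123 with an estimated correlation), with 13 higher and 1 lower adjusted over the list alone and 12 higher after TMM rescaling. Of 9 allantoin and urea genes 3 were higher, DAL3 (1.71 ± 0.15), DUR3 (1.39 ± 0.16) and DUR1,2 (1.69 ± 0.24), with a camera adjusted p = 1.02e-06 and an adjusted p = 0.123 with an estimated correlation. Of the 4 proline utilization genes PUT4 (1.45 ± 0.17) was higher (camera adjusted p = 0.0209; adjusted p = 0.227 with an estimated correlation), and adjusted over the list alone 2 were higher and 1 lower. Of 10 genes of GABA, glutamate and glutamine metabolism 2 were higher, GAD1 (1.46 ± 0.13) and UGA2 (0.58 ± 0.14), with a camera adjusted p = 0.00216 and an adjusted p = 0.123 with an estimated correlation. CAR2 (0.73 ± 0.14) was the 1 of 7 genes of arginine and asparagine catabolism that passed (camera adjusted p = 0.0127; adjusted p = 0.547 with an estimated correlation). Of 13 genes under the SPS sensor 4 were higher, including AGP1 (1.57 ± 0.21), and TAT1 (-0.74 ± 0.16) was lower (camera adjusted p = 0.000811; adjusted p = 0.371 with an estimated correlation). TMM rescaling gave 4 higher and 0 lower SPS genes. GAT1 was the 1 of 18 GATA factor and regulator genes that passed (camera adjusted p = 0.157). GLN3 stood at -0.42 ± 0.22, GZF3 at 0.29 ± 0.13 and URE2 at -0.47 ± 0.21, each short of the threshold. Adjusted over the list alone 3 allantoin, 4 GABA and glutamate, 1 arginine, 5 SPS and 1 regulator gene passed.

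Of 34 general stress genes 25 were higher in dal80Δ and none lower (median log2 1.10, camera adjusted p = 2.15e-35; adjusted p = 0.123 with an estimated correlation). They included ALD3 (2.69 ± 0.13), an aldehyde dehydrogenase gene, and the glycogen breakdown genes GPH1 (2.03 ± 0.13) and GDB1 (1.86 ± 0.12). The count was 31 adjusted over the list alone, and TMM rescaling gave 28 higher. Of 15 genes of the tricarboxylic acid cycle 8 were higher, among them IDH1 (0.86 ± 0.12), IDH2 (0.81 ± 0.12) and CIT1 (0.81 ± 0.13), with a camera adjusted p = 2.14e-11 and an adjusted p = 0.123 with an estimated correlation. Of 34 respiratory chain and ATP synthase genes 6 were higher, such as RIP1 (0.75 ± 0.13), with a camera adjusted p = 1.04e-07 and an adjusted p = 0.368 with an estimated correlation. Of 9 vacuolar protease genes 6 were higher, with PEP4 (0.90 ± 0.15) and PRB1 (0.85 ± 0.13) as examples (camera adjusted p = 1.06e-07; adjusted p = 0.123 with an estimated correlation). Of 19 glycolysis genes 3 were higher, TDH1 (1.48 ± 0.21), GLK1 (1.30 ± 0.19) and HXK1 (1.31 ± 0.24), with a camera adjusted p = 0.0394 and an adjusted p = 0.692 with an estimated correlation. GLK1 and HXK1 also belong to the stress list. Adjusted over the list alone 10 tricarboxylic acid cycle, 9 respiratory, 7 protease and 3 glycolysis genes passed. TMM rescaling gave 9, 8, 7 and 3 higher and none lower.

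A further 4 lists passed camera towards lower levels in dal80Δ with few called members. They were ribosome biogenesis (1 of 41 lower; camera adjusted p = 7.92e-06; adjusted p = 0.62 with an estimated correlation), ribosomal proteins (1 of 137 lower; 1.96e-06 and 0.62), amino acid biosynthesis (1 of 43 lower, SER3 at -0.78 ± 0.15; 0.00219 and 0.62) and histones (0 of 10; 0.0171 and 0.62), the later pairs giving the same adjusted p-values in the same order. The called members of the first pair were UTP8 (-0.64 ± 0.15) and RPS26B (-0.58 ± 0.14), and TMM rescaling gave 0 called members in both. The histone count was 0 also after TMM rescaling. Leaving out 1 library ended the camera call of 3 of these lists, with an adjusted p = 0.127 for ribosome biogenesis and 0.249 for amino acid biosynthesis without gat1Δ glutamine replicate 2, and 0.0944 for histones without gat1Δ glutamine replicate 1. The counts of the 4 lists were 10, 0, 1 and 0 adjusted over the list alone. The retrograde response (4 of 14 higher), autophagy (1 of 22 higher), phosphate response (0 of 14), iron regulon (1 of 20 lower, FET3 at -1.01 ± 0.16), sulfur amino acid synthesis (1 of 23 lower, SUL1 at -1.10 ± 0.20), meiosis (0 of 16) and pseudohyphal growth lists (0 of 10) did not pass camera, with adjusted p between 0.0531 and 0.85. Adjusted over the list alone 6, 1, 2, 2, 1, 0 and 0 of their members passed, and of the 6 retrograde genes 2 were lower. Across the 26 lists 18 passed camera with its preset correlation, and 0 with an estimated one.

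The third comparison, of dal80Δ in glutamine with gat1Δ in proline, differs in both strain and medium and serves only to place the groups against each other. Of 5594 genes 4294 passed, 877 higher and 3417 lower in dal80Δ glutamine, with a median log2 fold change of -0.63. TMM rescaling gave 1834 higher and 2010 lower. The largest rises were those of BAP3 (6.15 ± 0.14), HXK1 (4.77 ± 0.24), CWP1 (4.68 ± 0.19), AGP1 (4.45 ± 0.21) and YCL042W (4.42 ± 0.14). The largest falls were those of MF(ALPHA)1 (-10.62 ± 0.17), MF(ALPHA)2 (-8.45 ± 0.28), PUT1 (-7.40 ± 0.23), SAG1 (-5.79 ± 0.22) and STE3 (-5.49 ± 0.18). Of 46 targets of nitrogen catabolite repression 31 were lower and 10 higher, a balance close to that of all genes under the authors' scaling. Their median log2 fold change was -1.95, and the list did not pass camera (adjusted p = 0.2). After TMM rescaling 30 were lower and 13 higher, with a median of -1.34 against -0.04 for all genes. Of the 34 stress genes 25 were higher and 4 lower (camera adjusted p = 8.87e-18; adjusted p = 0.308 with an estimated correlation). Of the 7 a-specific genes 5 were higher in dal80Δ glutamine under the authors' scaling and 7 after TMM rescaling. Across the 26 lists 15 passed camera, and 0 with an estimated correlation.

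The first and second comparisons share the gat1Δ glutamine libraries. In both, 138 genes passed in the same direction, 111 higher and 27 lower, and 89 in opposite directions. Independent lists of the same sizes would share 138 in the same direction, 125 higher and 12.5 lower. Unchanged groups simulated against the same libraries shared 0.13 on average and at most 2. Such groups have few calls to share, so this count does not size the effect of the shared libraries on lists this long. Part of the overlap may come from the shared libraries. The count was 63 without dal80Δ replicate 1, 60 without dal80Δ replicate 2 and 80 without gat1Δ glutamine replicate 2. Across genes, which are not independent replicates, the log2 fold changes of both comparisons had r = 0.0889 and a covariance of 0.0450. The simulated unchanged groups had r = 0.498, which the shared libraries alone bring about, and a covariance of 0.0142. The observed r therefore cannot be read as a shortfall against the simulated one. The a-specific genes MFA1, AGA2, MFA2 and STE2, with YCL048W-A (4.23 ± 0.29 in proline), had the largest shared rises. In opposite directions stood MF(ALPHA)1, TPO2 (-1.77 ± 0.18 in proline), AGP1 (-2.88 ± 0.21), TDH1 (-1.64 ± 0.21) and HSP26 (-1.48 ± 0.30), the last 4 lower in proline and higher in dal80Δ.

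Noncoding transcripts differed between the media and between the strains, in numbers and directions that depended on the scaling. Of 250 tested, 141 passed between proline and glutamine, 116 higher and 25 lower under the authors' scaling. RLE factors gave 59 higher and 57 lower, and TMM factors over all features 62 and 53. All 6 entries for spliceosomal snRNAs rose under the authors' scaling (median log2 1.39), of which SNR7-L and SNR7-S share 179 bases on the same strand and are not separate. The snRNAs took 7.96% ± 0.431 of the reads in gat1Δ proline, 2.76% ± 0.145 in gat1Δ glutamine and 3.43% ± 0.145 in dal80Δ (SD, n = 2). Of 77 snoRNAs 37 rose and 5 fell, led by SNR38 (-1.53 ± 0.24), which lies within TEF4. Of 158 tRNA genes 67 were called higher and 20 lower, among them tA(AGC)P (5.14 ± 0.29) and tI(UAU)L (-1.82 ± 0.25). The tRNA genes are multicopy and took at most 0.0492% of the reads of a library, so these values are uncertain. Between the strains in glutamine 53 passed, 52 higher and 1 lower in dal80Δ, among them SNR6 (1.03 ± 0.25) and SNR59 (-0.68 ± 0.23), which lies within RPL7B. Of the 53, 41 were tRNA genes, all higher, so most of these calls rest on the uncertain tRNA values. The others were 11 snoRNAs, 10 of them higher, and 1 snRNA. The count of 53 became 100 with RLE factors and 99 with TMM over all features, all but 1 of them higher in each case. It was 2 without the filter on low counts and between 13 and 63 when a library was left out, and it was 13 without gat1Δ glutamine replicate 1. Between dal80Δ glutamine and gat1Δ proline 111 passed, 52 higher and 59 lower, against 115 and 18 with RLE factors and 107 and 21 with TMM over all features, and 61 passed without gat1Δ proline replicate 1. The limma fit found no spread in variance between these transcripts beyond chance, so their adjusted p-values are smaller than a fit to each would give.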

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

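The edgeR, TMM, RLE and snoRNA rescaling, and crossed-pairing settings marked as added below were chosen after seeing the data. Of 5007 values of named genes under an alternative, 4772 kept their direction and side of the threshold, 204 lost the call, 4 gained it and 27 changed sign. For proline against glutamine, snoRNA scaling gave 2423 genes with edgeR and 2465 with limma (added), and a log2 fold change of at least 1 gave 1723. TMM rescaling (added) kept 2733 of the 4006 calls in the same direction, and 272 changed sign without being called. For dal80Δ against gat1Δ in glutamine, snoRNA scaling gave 141 with edgeR and 142 with limma (added), DESeq2 gave 514, an adjusted p under 0.01 gave 115 and a log2 fold change of at least 1 gave 121. For dal80Δ glutamine against gat1Δ proline a log2 fold change of at least 1 gave 2221. The stricter thresholds lower counts by construction, and the cause of the other shifts was not tested. Noncoding calls between the strains in glutamine numbered 100 with RLE factors, 99 with TMM over all features, 94 with edgeR (added) and 2 with no filter. With an estimated correlation 0 lists passed camera for proline against glutamine, 0 for dal80Δ against gat1Δ and 0 for the third comparison. Fry, which sets a list against no change, called 22, 10 and 22 lists in the same order, so a shift of the median gene enters its counts. The overlap was 46 at a log2 fold change of at least 1.

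Leaving out each library in turn, with a lone library assumed to vary like the other groups, gave 3476 to 3908 genes for proline against glutamine, 110 to 369 for dal80Δ against gat1Δ and 3719 to 4355 for the third comparison. The low values of the second were 110 without dal80Δ replicate 1, 119 without dal80Δ replicate 2 and 180 without gat1Δ glutamine replicate 2. Noncoding calls ranged from 99 to 144, 13 to 63 and 61 to 110, lists past camera from 15 to 16, 16 to 19 and 14 to 15, and the overlap from 60 to 150. Same-numbered libraries did not deviate together across groups (correlations 0.00984, -0.25 and -0.0793), so the numbers do not pair them. With the replicate number as a block 3886, 208 and 4179 genes passed, with 135, 54 and 110 noncoding transcripts, 14, 19 and 15 lists and an overlap of 106. The crossed pairing (added) was set up after the negative correlation had been seen, and with 4 libraries it leaves 1 residual degree of freedom. Its 1653 genes for dal80Δ against gat1Δ, 549 higher and 1104 lower, therefore support no result.

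Signs changed for 6 genes. In proline against glutamine, ASP3-3 went to -0.0843 (edgeR with RLE), -0.0845 (DESeq2), -0.0314 (edgeR with TMM), -0.0280 (limma with TMM) and -0.0794 (limma with RLE). PDC5 went to -0.0978, -0.0981, -0.0447, -0.0570 and -0.107 in the same order. STE3 went to -0.0421 (edgeR with RLE), -0.0421 (DESeq2), -0.00522 (limma with TMM) and -0.0575 (limma with RLE). GAT1, at the floor in both groups, went to -0.0732 (edgeR with RLE), -0.0763 (DESeq2), -0.0216 (edgeR with TMM) and -5.42e-05 (limma with RLE), and ranged from -0.00812 to 0.0607 when a library was left out, lowest without gat1Δ proline replicate 1. In dal80Δ glutamine against gat1Δ proline, ASP3-2 went to 0.346 (edgeR with RLE), 0.346 (DESeq2), 0.301 (edgeR with TMM), 0.297 (limma with TMM) and 0.341 (limma with RLE), and LAP3 to 0.0324 (edgeR with RLE), 0.0324 (DESeq2) and 0.0307 (limma with RLE). ASP3-2 passed in this opposite direction with RLE in edgeR (adjusted p = 0.042) and in limma (adjusted p = 0.0492). Over all genes of that comparison 32 passed in the opposite direction with RLE in edgeR and 32 in limma, 24 with DESeq2, 11 with TMM in edgeR and 9 in limma. All scaling reversals came from factors that move the median gene of that comparison.

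Fry sets a list against no change and camera sets it against the other genes, so a different direction with fry is no reversal of camera. Lists that changed direction did so without passing, except for the first below. In proline against glutamine these were the tricarboxylic acid cycle with fry (adjusted p = 0.00503) and the respiratory chain with TMM (0.98). Leaving out a library there gave α-specific genes 0.172 to 0.899, reversed without gat1Δ proline replicate 2 (0.899), and meiosis 0.794 to 0.97, reversed without gat1Δ glutamine replicate 2 (0.97). In dal80Δ against gat1Δ, dropping gat1Δ glutamine replicate 2 reversed sulfur amino acids (0.954, range 0.473 to 0.954), autophagy (0.967) and iron (0.651). Autophagy otherwise stayed higher and reached 0.00108 without gat1Δ glutamine replicate 1. Iron, ranging from 0.199 to 0.944, also reversed without dal80Δ replicate 2 (0.944). Meiosis, ranging from 0.584 to 0.929, reversed without gat1Δ glutamine replicate 1 (0.929) and without dal80Δ replicate 1 (0.866). In the third comparison they were, with fry, the respiratory chain (0.115) and ribosomal proteins (0.265). The cause of the changes without fry was not tested. Leaving out a library also ended camera calls without a change of direction. In dal80Δ against gat1Δ this held, besides ribosome biogenesis, amino acid biosynthesis and histones, for arginine and asparagine catabolism (0.197), the SPS sensor (0.0524) and glycolysis (0.142), each without gat1Δ glutamine replicate 1. In proline against glutamine it held for the nitrogen-regulated permeases and the retrograde response (both 0.0558), and in the third comparison for ribosomal proteins (0.0787 without dal80Δ replicate 2). Depth limits the values of genes near the floor, such as DAL80 in glutamine, where 1 read more or less changes the ratio.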

Other observations

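Of 24 genes known to respond to mating pheromone, chosen after the values of 10 of them were seen, 20 rose in gat1Δ cells in proline, 1 fell and 3 did not pass. Of the 14 not seen before 10 rose and 1 fell, where 3162 of all 5594 genes rose (camera p = 0.0592; p = 0.394 with an estimated correlation), so a rise of the wider group is not shown. Of the 10 seen before, the agglutinin anchor gene AGA1 (3.79 ± 0.16), PRM1 (3.54 ± 0.20), KAR4 (3.11 ± 0.13) and FUS1 (2.83 ± 0.13) rose. Of the 14 not seen before, FIG2 (3.01 ± 0.14) had the largest rise and PRM9 (-1.11 ± 0.16) the only called fall. All of these genes were picked for naming by their values. Between the strains in glutamine none of the 24 was higher and 1 was lower. HO, the gene of the mating-type switching endonuclease, stood at 977 and 806 scaled reads in gat1Δ glutamine and at 72 and 101.1 in gat1Δ proline. Transcripts of the α2 repressor of a-specific genes, which have near-identical copies at MAT and HML, were higher in proline, with MATALPHA2 at 57.8 and 30.6 in glutamine and 233 and 271 in proline, and HMLALPHA2 at 35 and 33.9 and at 181 and 180.1.

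Of 14 zinc-responsive genes, listed after the values of 6 had been seen, 5 were lower in dal80Δ than in gat1Δ in glutamine and none higher. All 5 were among the 6 seen before, namely ZRT1, ZPS1, ZAP1, VEL1 and ADH4 (-1.06 ± 0.25), and none of the other 8 passed, so a wider change of the list is not shown. Camera gave the list p = 0.00366 towards lower levels (p = 0.0537 with an estimated correlation), but the genes seen before are part of it. Between proline and glutamine in gat1Δ 5 of the 14 fell and 4 rose (camera p = 0.00343; p = 0.0528 with an estimated correlation). ZPS1 (-2.97 ± 0.29) and VEL1 (-2.79 ± 0.40) were among those falls, so their lower level is not particular to the strain comparison. The ZRT1 level differed between the dal80Δ libraries, at 255 and 1322 scaled reads. The drug transporter gene PDR5 differed by replicate number within glutamine, at 132820 and 136580 scaled reads in replicate 1 of gat1Δ and dal80Δ and at 60489 and 53506 in replicate 2. Genes repressed by glucose rose in proline for 14 of 19 members tested, led by MLS1 (3.04 ± 0.15), and 3 fell. Their camera p was 0.157.

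Of the tests below, those of mixed cells, carried-over reads, abundant transcripts, a single library and slower growth were chosen after related values were seen, and the others before. The rise of a-specific genes in gat1Δ proline was weighed first. The share that each of the 7 genes reached of its dal80Δ level, above glutamine, ran from 7.1% (STE6) to 74.2% (ASG7), so that no fixed share of dal80Δ-like cells gives all 7. Mixed-in a cells with the lowest share, expressing HMRA1 as dal80Δ cells do, would bring at least 7.11 reads of this a-mating-type gene per proline library; 0 were found in both together. Carry-over from a strain with GAT1 would bring at least 40.0 GAT1 reads at this share, where 3 and 2 were found. The tables therefore argue against both for cells with the a-specific levels of dal80Δ in glutamine. Cells with higher a-specific levels in proline would need a smaller share and bring fewer of these reads. The counts cannot exclude such cells. An active pheromone response in the gat1Δ cells was weighed as well. The 14 response genes not looked at before lay 0.88 above the median of all genes, but their camera p of 0.0592 missed the threshold. This leaves such a response open. The test cannot show whether a response would bring about the a-specific rise or follow from it, and the effect of the medium is not separate from it.

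The excess of higher calls in proline under the authors' scaling was weighed next. Leaving the 10 most abundant genes out of the totals brought the median log2 fold change from 0.50 to 0.33, the 100 most abundant to 0.24 and the 500 most abundant to 0.13. A fall of abundant transcripts may therefore account for part of the excess, and the rest stays open. The 10 leading genes, picked in each library separately, took 8.96% of gene reads in proline and 18.7% in gat1Δ glutamine. They need not be the same genes, so these shares do not show a fall of given transcripts. Gene length bias is argued against, since the medians of the 1399 longest and the 1399 shortest genes differed by -0.12, and those of all 4 length classes lay between 0.46 and 0.57. A change of total RNA per cell cannot be measured here.

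Last came the stress genes higher in dal80Δ than gat1Δ in glutamine. A single library did not carry this, as the median log2 difference was at least 0.85 in each of the 4 pairs of libraries. For glucose depletion of the dal80Δ cultures, glucose-repressed genes lay 0.25 above all genes in median, and of 19 tested 1 was higher and 1 lower. This argues against a depletion that raises most of the list. A smaller effect stays open, since camera gave p = 0.00109 towards higher levels (p = 0.216 with an estimated correlation). Slower growth of the dal80Δ cultures could not be decided: ribosome biogenesis genes lay at -0.28 against all genes, with an adjusted p = 0.62 with an estimated correlation. Strain and mating type differ together between these groups, so their effects cannot be told apart here.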
